A study of Branchiostoma lanceolatum and Danio rerio with 33 samples.

How the data were processed

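The series holds 33 RNA-seq libraries of whole embryos, 15 of zebrafish and 18 of amphioxus. Embryos were fixed in RNAlater and RNA was extracted with a silica column kit, per the labels' protocols. The growth protocol is the same text for both species and describes zebrafish medium, so amphioxus culture conditions are not described here. The deposited values are raw read counts per feature. The submitters' processing notes name STAR and HTSeq, with no versions, and the build GRCz10 (danRer10). The amphioxus build is not given in the sources used here. Rows are versioned Ensembl transcripts in zebrafish and gene models in amphioxus, and strand settings are not given in the sources used here, so antisense or overlapping features cannot be told apart.

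Each table ends with 5 special rows of the counter, which were left out of library sizes and tests. Per 100 counts in feature rows, the no-feature row averaged 5.27 ± 0.595 (SD, n = 15) in zebrafish, the ambiguous row 26.2 ± 0.521 and the not-unique row 12.0 ± 1.14. In zebrafish, 1895 of 42002 transcripts with at least 50 counts had the same counts as another in every library, and 4782 of 21773 had a partner within 0.07 log2 units in every library. In amphioxus 886 of 39993 gene models had the same counts as another. Reads therefore appear to have been counted for more than 1 overlapping feature, so feature totals can hold a read more than once and special rows are not shares of reads.

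Groups were taken from the sample titles. Every pair of replicates differed by more than sampling noise (chi-square per degree of freedom of 3.00 at the lowest), so none was counted as a duplicate. For each species edgeR 4.0.16 in R 4.3.3 was run on the counts with TMM factors, the edgeR filter on low counts, 1 coefficient per group and quasi-likelihood tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. These choices were made before the data were examined. Log2 CPM used a prior count of 2. A model with a batch term for amphioxus was added after the counter's low-quality row was found to be 0 in controls 4 to 6 and FGF libraries. It has no FGF library in the other batch, so it cannot separate an FGF effect that differs between batches.

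Named features were, per comparison, the 2 with the highest and the 2 with the lowest log2 fold change among those past the threshold in the model fixed beforehand, with a mean of at least 5 CPM in the higher group and all treated libraries beyond all controls. Features called in all 4 treatments were ranked by their largest adjusted p in the model fixed beforehand. The rule's conditions on gene symbols could not be applied, because 0 of 58549 and 0 of 90927 identifiers matched the gene table given, which is of another amphioxus assembly. For the same reason 23 zebrafish and 5 amphioxus gene lists fixed beforehand, and the gene set tests on them, were not run. Where a group had 0 counts, a bound was set from 3 counts over the group, and with 1 to 3 counts a ratio with a 95% exact counting interval. In amphioxus the controls of the same batch were used, a choice made after the values over all 6 controls were seen. These intervals and bounds cover counting error only. A floor of 3 counts was 0.0878 CPM in the shallowest zebrafish library and 0.114 CPM in the shallowest amphioxus library.

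The models were tested on simulated counts with 200 changed features per treatment. In zebrafish, over 34681 features, 75% of 2-fold and 96% of 4-fold changes were recovered for FGF, 81% and 95% for Nodal, 86% and 97% for RA and 77% and 98% for Wnt, with at most 5.41% of calls false. In amphioxus with the batch term, over 29560 features, 52% and 75% were recovered for FGF, 53% and 89% for Nodal, 56% and 86% for RA and 57% and 90% for Wnt. Without the batch term, 4897 features were called for FGF, of which 96.7% were false. These values come from 1 simulated data set. In the unchanged groups described next, the model without the batch term called 3821 for FGF in simulation 1 and 0 in simulations 2 to 6. Unchanged groups were simulated 6 times for the overlaps. Every library, controls included, was drawn anew around the control means of its batch, with the spread estimated by the model. In all simulations that spread was 1 value per feature over all groups. Recovery and false shares therefore do not carry over to groups that varied more, amphioxus FGF with controls 4 to 6 and zebrafish Wnt.

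Alternatives were RLE or upper-quartile factors, no filter, DESeq2 1.42.0, 2 groups per fit, stricter thresholds, the 500 features with the smallest p, a replicate block, each library left out, controls of 1 batch, and counts thinned to 26278950 per library. Counting near-identical transcripts once, the batch term, and blocks coupling single FGF and control libraries of amphioxus were added later. The spread of a share was taken as a jackknife SD over left-out libraries. That choice was made after the values were seen: of 452 alternative shares, 43 lay outside it, whereas 268 lay outside the 95% binomial interval of the share. Python 3.11.15, scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for checks and plots.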

Results

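RNA was sequenced from whole embryos of the zebrafish *Danio rerio*, a vertebrate, at 80% epiboly, and of the amphioxus *Branchiostoma lanceolatum*, an invertebrate chordate, at 15 h. In each species, embryos in which the FGF, Nodal, retinoic acid (RA) or Wnt pathway had been modified were set against control embryos. FGF, Nodal and Wnt are families of secreted signalling proteins and RA is a vitamin A derivative. All act in axis formation and patterning of the early embryo. The labels name the pathway and do not say whether it was activated or blocked, so each direction below is that of the treated embryos against the controls. The zebrafish had 3 libraries in each of 5 groups. The amphioxus had 6 control libraries and 3 libraries in each of 4 treated groups. The labels do not say whether replicates came from separate clutches or cultures, so p-values measure the spread between these libraries, which may be technical. Each feature's spread was estimated over all groups of a species, not for the 2 groups compared. Within a group, the coefficient of variation beyond counting noise was taken over features with at least 50 counts. In zebrafish it was 0.053 for FGF, 0.071 for RA, 0.083 for controls, 0.132 for Nodal and 0.262 for Wnt. The value over all groups was 0.143. Tests may thus be too lenient for Wnt and too strict for FGF and RA.

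Library totals ran from 34158674 to 115511468 counts in zebrafish and from 26278950 to 53093109 in amphioxus. Depth followed group in zebrafish. The lowest total among control and RA libraries was 1.40 times the highest among FGF, Nodal and Wnt libraries. A sequencing batch, which no label gives, cannot be told apart from the FGF, Nodal and Wnt treatments in the zebrafish comparisons below. This also limits a comparison of their numbers of calls with that of RA. The zebrafish files held 58549 transcripts, of which 37669 had enough counts to be tested, and the amphioxus files held 90927 gene models, of which 32884 were tested. No identifier of either species matched the table of gene names used here, so features are named by identifier and their functions are not described. Of the 21773 zebrafish transcripts with at least 50 counts in every library, 4782 (22.0%) had a near-identical partner, so a number of transcripts overstates a number of genes.

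The amphioxus libraries fell into 2 batches. Controls 1 to 3 and all Nodal, RA and Wnt libraries had reads in the counter's low-quality row, whereas controls 4 to 6 and all FGF libraries had 0 there. Where it was filled, this row equalled the not-unique row (10896478 in control 1), so it is no measure of read quality. Control 4 had 34.9 not-unique reads per 100 feature counts and still 0 in the low-quality row. Counting therefore differed between the batches in at least this row. The first principal component, 71.2% of the variance, parted the libraries along the same line. Across gene models, which are not independent replicates, log2 abundance correlated at 0.972 or above between controls of the same batch and at a median of 0.815 between controls of different batches. Between the 2 sets of 3 controls, 14999 of 32884 gene models (45.6%) differed by edgeR's quasi-likelihood test, 4648 higher and 10351 lower in controls 4 to 6. Amphioxus values are therefore given from a model with a batch term, chosen after the data were seen, beside the model fixed beforehand, which has all 6 controls and no batch term. With the batch term, FGF is compared with controls 4 to 6, and Nodal, RA and Wnt with controls 1 to 3. The coefficient of variation within a group was 0.352 for controls 4 to 6 and 0.373 for FGF. For the other batch it was 0.064 for controls 1 to 3, 0.039 for Nodal, 0.108 for RA and 0.140 for Wnt. All tests in this model draw on the spread over all groups, at 0.208, so they may be too lenient for FGF and too strict for Nodal.

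**Figure D1:**
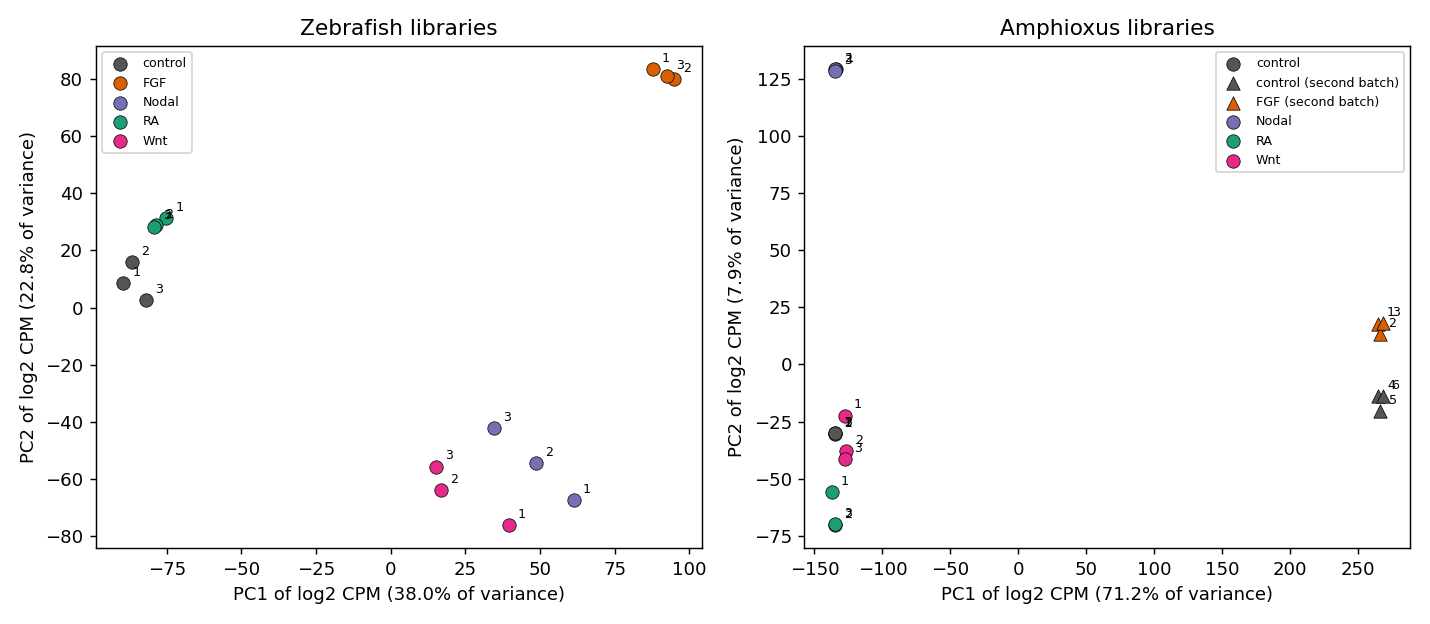
Principal components of log2 CPM, 1 point per library, numbered by replicate, for zebrafish (left) and amphioxus (right). In zebrafish PC1 (37.97% of variance) separates controls and RA from FGF, Nodal and Wnt; in amphioxus PC1 (71.2%) separates controls 4 to 6 and FGF, drawn as triangles, from the other libraries.

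The zebrafish FGF comparison asks which transcripts respond when FGF signalling is modified. Transcript ENSDART00000173054.1 rose from 0 counts in all 3 controls to 5.52 ± 1.11 CPM (SD, n = 3), at least 578-fold against a floor of 3 counts over the controls (at least 364-fold without control replicate 3). ENSDART00000046253.4 rose from 0.00918 ± 0.00874 to 17.04 ± 4.50 CPM, a ratio of 1736 with a 95% counting interval of 593 to 8425. The ratio was 3278 (588 to 129519) without control replicate 3. ENSDART00000155835.1 fell from 18.3 ± 0.863 to 0.267 ± 0.119 CPM (log2 fold change -6.08 ± 0.21 SE, adjusted p = 1.53e-11). ENSDART00000112364.3 fell from 9.33 ± 0.919 to 0.153 ± 0.0705 CPM (-5.92 ± 0.34, adjusted p = 1.69e-09). In all, 21200 transcripts (56.3% of those tested) differed at the 0.05 level, 11048 higher and 10152 lower. At least 2-fold changes were found for 5634 higher and 3412 lower transcripts, and at least 8-fold changes for 728 and 229. Adjusted p-values throughout are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

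In the zebrafish Nodal comparison, ENSDART00000065136.3 rose from 0.0297 ± 0.0116 to 13.5 ± 8.81 CPM (log2 fold change 8.78 ± 0.93 SE, adjusted p = 2.09e-06, and 8.19 without Nodal replicate 2). ENSDART00000163079.1 rose from 0.182 ± 0.0580 to 6.86 ± 5.78 CPM (5.22 ± 0.57, adjusted p = 2.64e-06, and 4.26 without Nodal replicate 1). ENSDART00000064678.5 fell from 14.3 ± 1.40 to 0.0145 ± 0.0132 CPM, a ratio of 931 (95% counting interval 257 to 7687). ENSDART00000052569.6 fell from 5.13 ± 0.474 to 0.0205 ± 0.0185 CPM, a ratio of 224 (76.6 to 1089), which was 386 (69.2 to 15259) without Nodal replicate 2. With Nodal, 18993 transcripts (50.4%) differed from the controls, 9397 higher and 9596 lower, of which 3554 and 3668 differed at least 2-fold.

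In the zebrafish RA comparison, fewer transcripts passed the threshold. ENSDART00000110347.2 rose from 0.117 ± 0.0245 to 30.1 ± 1.44 CPM (log2 fold change 7.99 ± 0.18 SE, adjusted p = 2.31e-13). ENSDART00000065136.3, which also rose with Nodal, rose to 17.3 ± 13.4 CPM (9.12 ± 0.93, adjusted p = 4.37e-06, and 8.27 without RA replicate 3). The near-identical transcripts ENSDART00000103997.4 and ENSDART00000169402.1, whose reads cannot be told apart, fell from 19.8 ± 0.581 to 2.65 ± 0.796 and from 19.8 ± 0.597 to 2.64 ± 0.792 CPM (both -2.91 ± 0.19). RA changed 4922 transcripts (13.1%), 2870 higher and 2052 lower. At least 8-fold changes were nearly all increases, with 198 higher and 2 lower. The count fell to 3054 with every library thinned to one total and rose to 10605 with RA and control fitted alone. That last fit takes its spread from RA and control libraries only, which varied less (0.071 and 0.083) than all groups together (0.143). The 4922 thus depends on libraries of other treatments, and fewer calls need not mean a weaker response. How much of the rise the spread accounts for was not tested. The count was 3129 without RA replicate 2 and 3193 without control replicate 3.

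In the zebrafish Wnt comparison, the same ENSDART00000065136.3 rose to 77.1 ± 49.0 CPM (log2 fold change 11.28 ± 0.93 SE, adjusted p = 2.67e-07, and 10.63 without Wnt replicate 1), and ENSDART00000023550.10 rose from 8.01 ± 1.32 to 146 ± 18.5 CPM (4.19 ± 0.18, adjusted p = 3.70e-10). The pair that fell with RA, ENSDART00000103997.4 and ENSDART00000169402.1, fell further, to 0.0564 ± 0.0619 CPM each (both -8.40 on the log2 scale, adjusted p = 2.09e-10). Without Wnt replicate 1 those values were -9.57 and -9.56. With Wnt, 19189 transcripts (50.9%) differed from the controls, 9764 higher and 9425 lower, of which 3978 and 3238 differed at least 2-fold. Wnt replicate 1 correlated at 0.970 and 0.972 with the other Wnt libraries, which correlated at 0.990 with each other.

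Many zebrafish transcripts changed in more than 1 treatment. Transcripts ENSDART00000089206.5 and ENSDART00000134157.2, which had the same counts, rose in all 4 treatments, by 5.11 ± 0.21 (log2, SE) with FGF, 4.60 ± 0.21 with Nodal, 4.49 ± 0.20 with RA and 4.47 ± 0.21 with Wnt. ENSDART00000125344.2 fell in all 4, from 12.3 CPM in controls to between 1.15 CPM with FGF and 3.44 CPM with RA. Of 30313 transcripts called in any treatment, 20453 (67.5%) were called in 2 or more, against 64.4% for independent lists of the same sizes. Among changes of at least 2-fold the share was 50.1% of 14539, against 24.9% for independent lists. In all 4 treatments, 868 transcripts rose, 626 fell and 386 moved in both directions, against 711 in all for independent lists. Independent lists take no account of the controls that the 4 comparisons share, so they are not a chance level.

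The commonest pattern was a call with FGF, Nodal and Wnt and none with RA, which by itself does not show that RA differed, with 4320 transcripts lower in those 3 and 3758 higher, against 563 and 621 for independent lists. Of transcripts called in both members of a pair, 94.97% moved the same way for FGF and Nodal, 92.2% for FGF and Wnt and 96.8% for Nodal and Wnt. For pairs with RA the shares were 82.2% with FGF, 76.9% with Nodal and 80.5% with Wnt. Comparisons with the same controls share their chance values, so unchanged groups were simulated together with a shared set of simulated controls. The covariance of log2 fold changes was 0.665, 0.559 and 0.592 for the first 3 pairs and 0.251, 0.184 and 0.195 for the pairs with RA, against 0.024 in the simulations. The correlations across transcripts, which are not independent replicates, were 0.61, 0.55 and 0.68 and 0.37, 0.31 and 0.35, against 0.42 to 0.46 simulated. The 3 zebrafish controls are too few to split, so part of each overlap may come from the shared controls. Transcripts called in 1 treatment alone, and different from the other 3 treatments by direct test, numbered 1668 for FGF, 526 for Nodal, 257 for RA and 988 for Wnt. The Wnt number was 389 without Wnt replicate 1 and 621 without Nodal replicate 2, and the Nodal number 197 without Nodal replicate 1 and 228 without Nodal replicate 2.

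**Figure D2:**
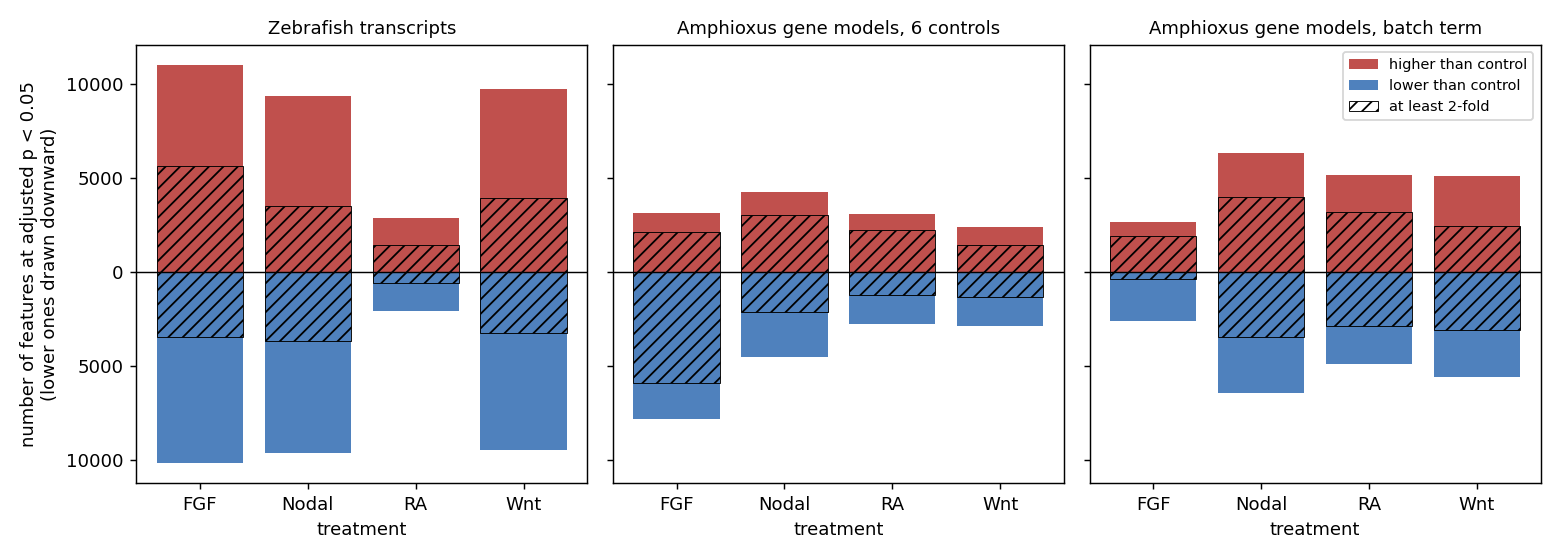
Number of features higher (upward bars) and lower (downward bars) than control at an adjusted p under 0.05 in each treatment, with changes of at least 2-fold hatched. For amphioxus FGF, 7795 gene models were lower with all 6 controls and no batch term and 2570 with the batch term.

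The amphioxus FGF comparison depended on which controls were used. BL39188 rose from 0.132 ± 0.0884 CPM in controls 4 to 6 to 7.20 ± 5.18 CPM (SD, n = 3 each), with a log2 fold change of 5.75 ± 0.63 SE with the batch term (adjusted p = 1.39e-05) and 5.15 ± 0.61 without it. Leaving out FGF replicate 1 gave 4.97 and 4.38. BL08439 rose from 0.160 ± 0.142 to 5.44 ± 4.11 CPM (5.05 ± 0.63 with the batch term, adjusted p = 4.80e-05), with 5.75 without control replicate 4, 4.47 without control replicate 5 and 4.25 without FGF replicate 1. BL79092 fell by 1.26 ± 0.26 on the log2 scale with the batch term (adjusted p = 0.00302), against -6.53 ± 1.62 without it. It did not pass with the batch term when control replicate 5 was left out (-1.02, adjusted p = 0.0607). BL58885 had 0 counts in every FGF library and 13.0 ± 14.3 CPM over the 6 controls, nearly all in controls 1 to 3. Controls 4 to 6 held 3 counts, so no fold is given against them, and it did not pass the test with the batch term (adjusted p = 0.124). Without the batch term, neither BL58885 nor BL79092 passed when any 1 FGF library was left out (adjusted p from 0.0566 to 0.0781). In the model with the batch term 5261 gene models changed, 2691 higher and 2570 lower. Without it 10954 passed the threshold, 3159 higher and 7795 lower. In 1 simulated data set with the same batches and 200 changed features per treatment, 96.7% of the FGF calls made without the batch term were false. With it 7.30% were false. The first value was unstable and does not give a false share for the real data. In the unchanged groups, the model without the batch term called 3821 for FGF in simulation 1 and 0 in simulations 2 to 6. No simulation held the coupling of FGF and control libraries described below. All simulated libraries had the spread estimated over all groups, at 0.208, below that of controls 4 to 6 (0.352) and FGF (0.373). The 7.30% therefore does not carry over to the real FGF calls either. FGF against controls 4 to 6 alone gave 4247. The batch term model takes no account of a coupling of single FGF and control libraries that the labels do not give but the expression values show. With each FGF library in a block with the control it deviated with, 9916 passed, 5101 higher and 4815 lower, among them 5259 of the 5261. The couples were read from the same data, and the 5 other one-to-one matchings gave 5186 to 6883. Without the batch term the count was 1190 with FGF and control fitted alone, 2659, 3103 and 3312 without FGF replicates 1, 2 and 3, and 7171 without control replicate 2.

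Changes of at least 8-fold downward numbered 4761 for amphioxus FGF without the batch term and 23 with it. Changes of at least 2-fold were mostly increases with the batch term, 1931 higher against 342 lower. Upper-quartile scaling, in the model without the batch term, moved the share of FGF calls that were higher from 28.8% to 42.4%.

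In the amphioxus Nodal comparison, BL19836 and BL84950 rose from 0.0158 ± 0.0141 CPM in controls 1 to 3, which held 2 counts of each, to 6.25 ± 0.878 and 6.17 ± 0.958 CPM (adjusted p with the batch term 1.64e-07 and 1.76e-07). The ratios were 376 (95% counting interval 104 to 3113) and 371 (102 to 3070), against 682 and 673 over all 6 controls, where controls 4 to 6 held no count. BL19565 fell from 18.6 ± 0.601 to 0.0667 ± 0.0336 CPM (log2 fold change -8.10 ± 0.33 SE with the batch term, adjusted p = 2.28e-11). BL01012 fell from 95.9 ± 2.95 to 0.555 ± 0.0787 CPM (-7.41 ± 0.16, adjusted p = 3.44e-15). A total of 12757 gene models changed with the batch term, 6323 higher and 6434 lower, of which 3993 and 3411 changed at least 2-fold. Without it 8768 changed, 4274 higher and 4494 lower.

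In the amphioxus RA comparison, BL42665 and BL71432, which had the same counts, rose from 0.00901 ± 0.0156 CPM in controls 1 to 3 to 5.32 ± 0.819 CPM (adjusted p with the batch term 5.26e-07). Their only control count was in control 1, so the ratio of 654 has a wide 95% counting interval, 117 to 25860, and it was 1186 over all 6 controls. The ratio was 391 (69.97 to 15463) without control replicate 2, and the rise at least 152-fold without control replicate 1, when no control count is left. BL35451 fell from 14.8 ± 1.65 to 0.0136 ± 0.0236 CPM, a ratio of 1073 (297 to 8867) with 2 counts in the RA libraries (adjusted p = 4.21e-09). That ratio was 672 (186 to 5551) without RA replicate 3, and the fall at least 473-fold without RA replicate 2, which held both counts. BL17425 fell from 2.61 ± 0.567 to 0.517 ± 0.137 CPM (log2 fold change -2.35 ± 0.31 SE with the batch term, adjusted p = 2.49e-05). It met the rule of 5 CPM only over all 6 controls (6.82 ± 5.04 CPM). With the batch term it is not among the strongest falls, since 624 gene models fell at least 8-fold with RA. RA changed 10058 gene models with the batch term, 5181 higher and 4877 lower, and without it 5843, 3117 higher and 2726 lower. Upper-quartile scaling, without the batch term, moved the share of RA calls that were higher from 53.3% to 32.2%. The count without the batch term was 2761 without RA replicate 2 and 3027 without RA replicate 3.

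In the amphioxus Wnt comparison, BL09413 rose from 0.172 ± 0.0627 CPM in controls 1 to 3 to 16.8 ± 7.45 CPM (log2 fold change 6.62 ± 0.59 SE with the batch term, adjusted p = 1.16e-06) and BL45127 from 0.151 ± 0.0392 to 7.11 ± 3.09 CPM (5.54 ± 0.43, adjusted p = 2.03e-06). BL35451, which fell with RA, also fell with Wnt, to 0.0152 ± 0.0132 CPM, a ratio of 1042 (95% counting interval 288 to 8609), or 653 (180 to 5393) without Wnt replicate 1 (adjusted p = 1.09e-08). BL35107 fell from 3.74 ± 0.487 to 0.0671 ± 0.0416 CPM (-5.78 ± 1.46, adjusted p = 0.00602). It met the rule of 5 CPM only over all 6 controls (6.50 ± 9.17 CPM), where control 6, of the other batch, was at 25.059 CPM. Wnt changed 10711 gene models with the batch term, 5131 higher and 5580 lower, and without it 5252, 2415 higher and 2837 lower. Upper-quartile scaling, without the batch term, moved the share of Wnt calls that were higher from 46.0% to 28.3%. The count without the batch term was 3056, 2683 and 3126 without Wnt replicates 1, 2 and 3.

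Across amphioxus treatments, RA and Wnt moved gene models together most often. Of gene models called in both, 94.5% moved the same way with the batch term and 94.9% without it. For Nodal the shares with the batch term were 77.0% with RA and 79.4% with Wnt. For FGF they were 75.0% with Nodal, 43.3% with RA and 46.4% with Wnt, and 68.4%, 43.1% and 52.3% without the batch term. With the batch term, Nodal, RA and Wnt share controls, which alone gives common signs. Among the top 500 by p in simulated unchanged groups, RA and Wnt had on average 83.2 with the same sign and 0.333 opposite. For FGF and Nodal those means were 8.83 and 8.67. Shares of pairs with and without FGF are therefore not comparable. A high share among Nodal, RA and Wnt does not by itself show a common response. Single libraries carried some of the lower shares past 50%. The share for FGF and Wnt with the batch term was 50.4% without control replicate 5. The share for FGF and RA with the batch term stayed below 50%, from 38.3% to 47.1% over left-out libraries. Without the batch term, the share for FGF and RA was 50.3% without control replicate 4 and 51.5% without FGF replicate 3. Opposite directions were taken by 962 gene models with FGF and RA and by 1094 with FGF and Wnt under the batch term, 1.20 and 1.28 times the numbers for independent lists, against 0.912 and 1.11 times for the same direction. Among changes of at least 2-fold these ratios were 1.60 and 1.38, against 0.966 and 1.17. The covariance of log2 fold changes with the batch term, less that of simulated unchanged groups, was 0.759 for Nodal and RA, 0.783 for Nodal and Wnt and 0.839 for RA and Wnt. It was 0.128 for FGF and Nodal, -0.043 for FGF and RA and -0.026 for FGF and Wnt. With the batch term FGF shares no controls with the other treatments, and its highest simulated covariance was 0.00298. When the 6 controls were split by batch so that Nodal, RA and Wnt were each set against a different batch from its partner, the correlations lay between -0.014 and 0.004. Those values also hold the difference between batches.

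**Figure D3:**
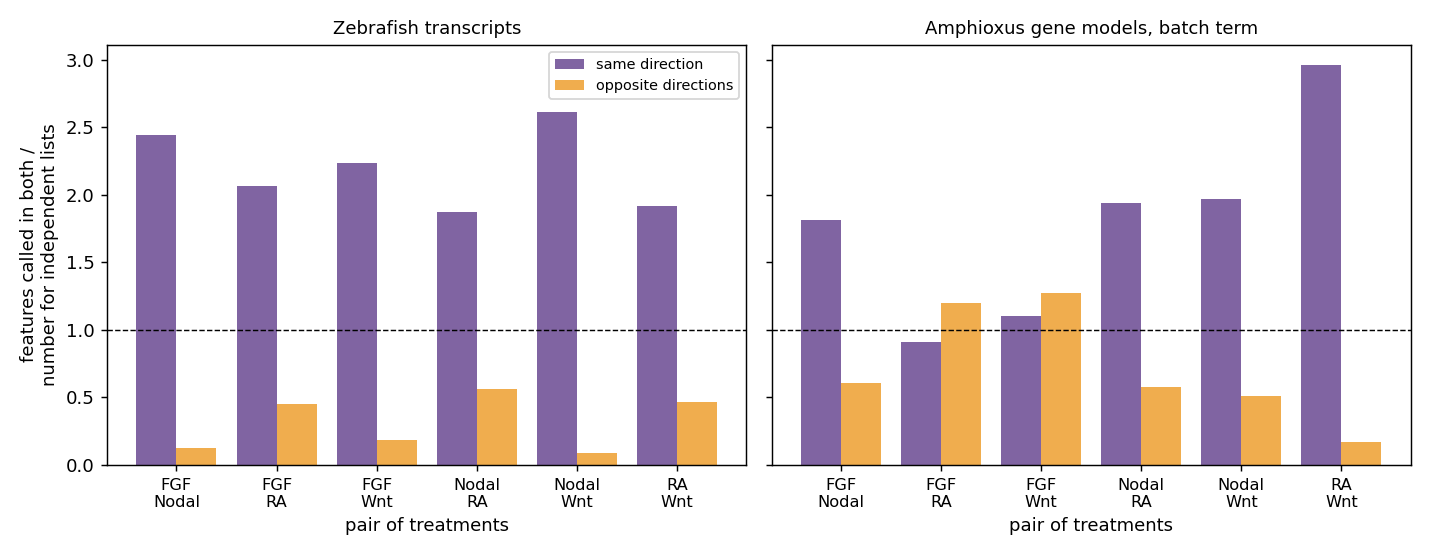
Number of features called in both treatments of a pair, in the same direction or in opposite directions, divided by the number for independent lists (dashed line at 1), for zebrafish (left) and for amphioxus with the batch term (right). In zebrafish the same-direction ratio is highest for Nodal and Wnt, at 2.61, and in amphioxus for RA and Wnt, at 2.96.

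The share of features changed by more than 1 treatment was compared between species without a test, since each species is 1 case. Over the 4 treatments, 51.2% of 22569 called amphioxus gene models were called in 2 or more with the batch term (independent lists 44.6%), and 33.8% of 21275 without it (35.2%), against 67.5% in zebrafish. These shares move with the number of calls. Among the 500 features with the smallest p in each treatment, the share was 26.6% in zebrafish and 16.8% in amphioxus with the batch term, against means of 16.5% and 13.0% in simulated unchanged groups. FGF has its own controls in amphioxus but not in zebrafish. For Nodal, RA and Wnt, which share 3 controls in each species, the share called in 2 or more was 55.5% in zebrafish and 45.4% in amphioxus, with jackknife SDs of 10.6 and 14.2 percentage points over left-out libraries, so the difference was smaller than either spread. Among changes of at least 2-fold these shares were 40.5% and 39.0%, against 14.0% and 20.3% for independent lists.

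**Figure D4:**
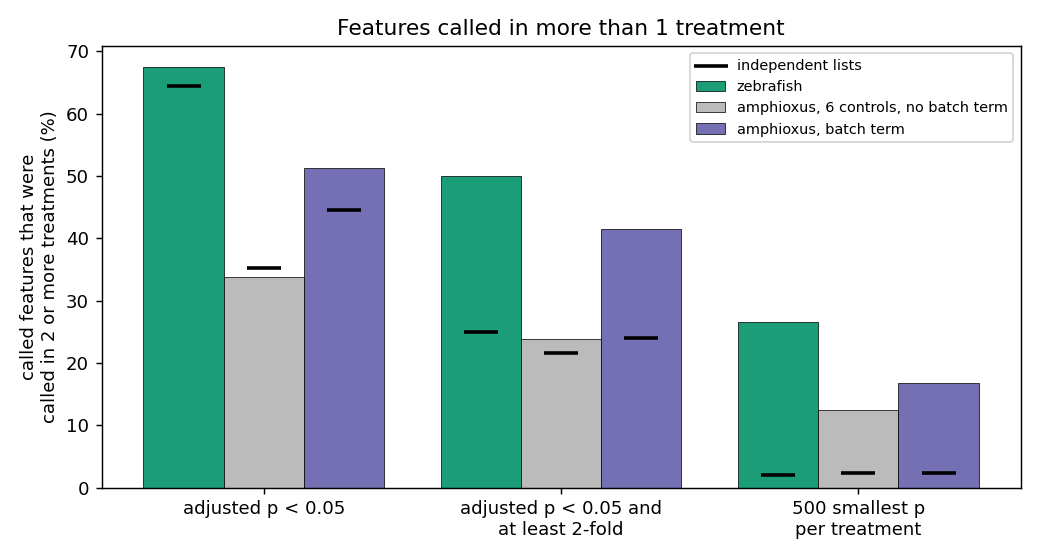
Percent of called features that were called in 2 or more of the 4 treatments, under 3 ways of making the lists, with the percent for independent lists as black dashes. With at least 2-fold changes the zebrafish share is 50.1% and the amphioxus share 41.4% with the batch term and 23.8% without it.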

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

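Tests chosen only after the result was seen were those of a sequencing batch in zebrafish, of depth as the source of a common direction, of a wrong label for zebrafish Wnt replicate 1 and of preparation or counting in amphioxus.

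Among 21 measures of the 6 amphioxus controls, 4 had a library far from the others. Chance gives about 1 in 20, but the measures are not independent and no excess is read from the 4. Control 2 had a total of 51441715 counts, against 32623504 to 38443153 in the others. BL42665 and BL71432, which share their counts, were at 0.027044 CPM in control 1, which is 1 count, and 0 in the others. They are 1 measurement, and a lone count stands apart by construction. BL35107 was at 25.059 CPM in control 6 and at most 4.29 CPM in the others.

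Outside the tested rows, zebrafish reads that met no feature were higher in every treated library than in any control. Per 100 feature counts they averaged 5.9997 with FGF, 5.3454 with Nodal, 4.9067 with RA and 5.552 with Wnt, against 4.54 in controls. The not-unique row with FGF averaged 13.189, against 11.6 in controls. Other rows were lower in every treated library than in any control of the same batch. The ambiguous row averaged 25.9 with zebrafish FGF, 25.7 with Nodal and 25.9 with Wnt, against 26.8 in controls. The amphioxus not-unique row averaged 27.2 with Nodal, 27.3 with RA and 26.4 with Wnt, against 28.5 in controls 1 to 3, and the no-feature row 3.83 with Wnt, against 4.25. The exact two-sided permutation p of each was 0.1, the smallest that 3 against 3 libraries allow, and 0.2 after Benjamini-Hochberg adjustment over 24 comparisons.

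The difference between amphioxus controls 1 to 3 and 4 to 6 bore on the numbers of calls in the model without a batch term, and most on FGF. It also bore on shares and correlations. The share called in 2 or more treatments was 33.8% without the batch term and 51.2% with it. Common FGF and Wnt calls had the same sign in 52.3% and 46.4%. The correlation of FGF and Nodal fold changes was -0.142 without the term and 0.108 with it. The same-sign share of RA and Wnt hardly moved, at 94.9% without the batch term and 94.5% with it. Depth is argued against, since after thinning the median correlation between batches was 0.826, below the lowest within a batch, 0.972. A change limited to features with few counts is argued against too, since 6.89% of 3773 gene models of at least 50 CPM differed at least 2-fold (95% exact interval 6.10 to 7.75), although the difference was far commoner among the others, 37.3% of 29111. Gene models with at least 100 counts in 1 batch and none in the other numbered 1798 for controls 1 to 3 and 6 for controls 4 to 6, a ratio of 299.7. Library preparation or counting that differed between the batches may therefore explain part of the difference. Counting did differ in the low-quality row, which equalled the not-unique row in the batch of controls 1 to 3 and was 0 in the other. Whether that reached the feature counts was not tested. No biological explanation was tested, because the labels give none.

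Zebrafish FGF, Nodal and Wnt moved transcripts together. Noise of the shared controls, as simulated, is argued against as the only source by a median covariance of 0.592, against at most 0.0254 simulated. The simulated controls were drawn anew, so a deviation of the real controls beyond the modelled spread is not covered. Depth stays open, because the lowest share with the same sign after thinning, 93.4%, decides nothing. The top 500 transcripts of unchanged groups, simulated with a shared set of simulated controls, shared the sign in 99.5% or more on average, not in the 50% assumed. By the planned test, after thinning the share called in 2 or more treatments exceeded that of independent lists by 5.49 percentage points, above the 5 set beforehand but within the share's jackknife SD of 9.96, chosen after the value was seen. A sequencing batch cannot be told apart from the treatments, because the totals of control and RA libraries were all at least 1.40 times those of the other groups, and a response common to the 3 pathways also stays open.

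Zebrafish Wnt replicate 1 stood apart from the other Wnt libraries. Its lowest correlation with them was above its highest with a library of another group by 0.0168, which argues against a library of another treatment in this series. Wnt replicate 2 nevertheless correlated with a Nodal library at 0.974, above its 0.970 with Wnt replicate 1. A few transcripts taking many counts stay open: without its 100 most abundant transcripts its highest correlation with a Wnt library was 0.972, as with them, so that test decides nothing. The 100 took 22.5% of its counts, against 17.5% to 21.2% in the other zebrafish libraries, its scaling factor was 0.822, and no biological explanation was tested.

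Other splits of the libraries were counted for each comparison. In zebrafish, 1 of 10 splits, the real one, gave as many calls for each treatment, with 21200, 18993, 4922 and 19189 calls and at most 0 in another split. So few splits allow no share under 0.05. In amphioxus without the batch term, all 84 splits were run, after a smaller draw that held the same split by batch had been seen. For FGF 2 of 84 splits gave as many calls as the 10954 of the real one, for Nodal 2 (8768), for RA 2 (5843) and for Wnt 3 (5252). These splits exchange libraries of different batches, so their share does not show whether chance can be excluded. The split that followed the batch gave more than the real one each time, with 18314, 16959, 16695 and 15972 calls, which points to the structure of the samples. Without that split the highest were 8856, 4357, 4614 and 5493, the last above the real Wnt number and reached with controls 1 to 3 taken as the treated set. Within batches, with the batch term, 1 of 10 splits gave as many as the real 5261, 12757, 10058 and 10711 calls, which again allows no share under 0.05. The highest other split gave 2823 for FGF, with control 4, FGF 1 and FGF 2 taken as the treated set, and 0 for Nodal, RA and Wnt. For FGF the calls of other splits followed the couples of FGF and control libraries described under other observations. The 3 splits that part every couple gave 0 calls and the 6 that keep 2 couples together 1038 to 2823, whereas the real split, which also parts all 3, gave 5261.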

How the results depend on the processing

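Added after seeing the data were the batch term, thinning for numbers of calls, counting near-identical transcripts once, blocks for couples of FGF and control libraries, and every alternative for common signs, for calls in 1 treatment alone and for calls in 2 or more of Nodal, RA and Wnt. Across the named features, 583 of 596 alternative fold changes kept their direction and their side of the threshold, 13 lost the threshold and 0 reversed. The 13 belonged to BL58885 and BL79092 with FGF. RLE factors alone, DESeq2 and counting near-identical transcripts once moved no number of calls by over 1.5 times and no share by over its jackknife SD. Where values moved below, the cause was not tested unless the alternative itself uses fewer samples or a stricter threshold. Of the numbers of calls, thinning to one depth moved that of zebrafish RA alone by over 1.5 times. The alternatives planned for gene lists were not run, and the split of the controls has its values in the results.

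With a log2 fold change of at least 1, the number called was 9046 for zebrafish FGF, 7222 for Nodal, 2012 for RA, 7216 for Wnt, 5135 for amphioxus Nodal, 3494 for RA and 2814 for Wnt. The share called in 2 or more treatments was 50.1% for zebrafish. The share called in 2 or more of Nodal, RA and Wnt was 40.5% for zebrafish. The share of common calls with the same sign was 86.2% for zebrafish FGF and RA, 90.5% for RA and Wnt, 46.1% for amphioxus FGF and Wnt, 84.9% for Nodal and RA and 91.3% for Nodal and Wnt. With an adjusted p under 0.01, the number called was 2494 for zebrafish RA, 1921 for amphioxus FGF, 5101 for Nodal, 2757 for RA and 2404 for Wnt. Common calls had the same sign in 83.9% for amphioxus FGF and Nodal and 62.5% for FGF and Wnt. Calls in 1 treatment alone numbered 222 for zebrafish Nodal, 447 for Wnt, 478 for amphioxus FGF, 290 for RA and 149 for Wnt. With the top 500 features by p, the share called in 2 or more treatments was 26.6% for zebrafish and 12.5% for amphioxus. Among Nodal, RA and Wnt the share was 20.8% for zebrafish and 9.78% for amphioxus. With 2 groups per fit, the number called was 10605 for zebrafish RA, 1190 for amphioxus FGF, 5716 for Nodal, 2713 for RA and 2223 for Wnt. Same-sign shares of common calls were 77.9% for zebrafish FGF and RA, 86.7% for amphioxus FGF and Nodal and 66.0% for FGF and Wnt.

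With no low-count filter, the share of common calls with the same sign was 87.3% for amphioxus Nodal and Wnt. With upper-quartile factors, the share of common calls with the same sign was 32.8% for amphioxus FGF and RA, 40.5% for FGF and Wnt and 87.6% for Nodal and Wnt. Those factors shifted log2 fold changes by up to 0.106 in zebrafish and by 0.254, -0.145, -0.242 and -0.204 for amphioxus FGF, Nodal, RA and Wnt. With thinned counts, the number called was 3054 for zebrafish RA.

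With controls 1 to 3 only, the number called was 20607 for amphioxus FGF, 14249 for Nodal, 11821 for RA and 12437 for Wnt. In 2 or more treatments the share was 64.0% for amphioxus. For Nodal, RA and Wnt alone the share in 2 or more was 49.3% for amphioxus. The share of common calls with the same sign was 68.4% for amphioxus FGF and RA and 73.9% for FGF and Wnt. The number in 1 treatment alone was 568 for amphioxus Wnt. With controls 4 to 6 only, the number called was 4247 for amphioxus FGF, 18462 for Nodal, 17025 for RA and 15988 for Wnt. Calls in 2 or more treatments made up 69.6% for amphioxus. The share called in 2 or more of Nodal, RA and Wnt was 66.6% for amphioxus. Common calls had the same sign in 60.7% for amphioxus FGF and RA, 63.9% for FGF and Wnt, 93.3% for Nodal and RA, 94.1% for Nodal and Wnt and 97.8% for RA and Wnt. Alone in 1 treatment stood 509 for amphioxus FGF, 763 for RA and 523 for Wnt. With the batch term, the number called was 5261 for amphioxus FGF, 10058 for RA and 10711 for Wnt. The share called in 2 or more treatments was 51.2% for amphioxus. Same-sign shares of common calls were 46.4% for amphioxus FGF and Wnt. Calls in 1 treatment alone numbered 375 for amphioxus FGF and 532 for Wnt. With the batch term and top 500 by p, the share called in 2 or more treatments was 16.8% for amphioxus. Among Nodal, RA and Wnt the share was 16.6% for amphioxus. With the batch term and RLE factors, the share called in 2 or more treatments was 50.9% for amphioxus.

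Libraries with the same replicate number, from 1 to 3, did not deviate together. The correlations of deviations ran from -0.134 to 0.108 in zebrafish and from -0.0367 to 0.0986 in amphioxus, so equal numbers give no pairing. This check did not set FGF libraries against controls 4 to 6, the controls of their batch. There the couples do follow the numbering order, FGF 1 with control 4, FGF 2 with control 5 and FGF 3 with control 6. The block moved no zebrafish number of calls by over 1.5 times. In amphioxus it leaves out controls 4 to 6, so it does not hold the couples of FGF libraries with those controls. With the replicate block, the number called was 20310 for amphioxus FGF, 13966 for Nodal, 11490 for RA and 12071 for Wnt. In 2 or more treatments the share was 62.8% for amphioxus. For Nodal, RA and Wnt alone the share in 2 or more was 48.4% for amphioxus. The share of common calls with the same sign was 68.9% for amphioxus FGF and RA and 74.6% for FGF and Wnt. The number in 1 treatment alone was 549 for amphioxus Wnt.

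With 1 library left out at a time, these results moved. Calls for zebrafish RA ran from 3129 to 3577, with 3193 without control replicate 3 and 3129 without RA replicate 2. Zebrafish Nodal alone ran from 197 to 732, with 197 without Nodal replicate 1 and 228 without Nodal replicate 2. Zebrafish Wnt alone ran from 389 to 1462, with 621 without Nodal replicate 2 and 389 without Wnt replicate 1. Calls for amphioxus FGF ran from 2659 to 13300, with 7171 without control replicate 2, 2659 without FGF replicate 1, 3103 without FGF replicate 2 and 3312 without FGF replicate 3. Calls for amphioxus RA ran from 2761 to 6234, with 2761 without RA replicate 2 and 3027 without RA replicate 3. Calls for amphioxus Wnt ran from 2683 to 5584, with 3056 without Wnt replicate 1, 2683 without Wnt replicate 2 and 3126 without Wnt replicate 3. Same-sign calls for amphioxus FGF and RA ran from 41.5% to 51.5%, with 50.3% without control replicate 4 and 51.5% without FGF replicate 3. Same-sign calls for amphioxus FGF and Wnt ran from 54.1% to 62.3%, with 62.3% without FGF replicate 3. Amphioxus FGF alone ran from 623 to 5948, with 623 without FGF replicate 1, 758 without FGF replicate 2 and 789 without FGF replicate 3. Amphioxus RA alone ran from 263 to 583, with 273 without RA replicate 2 and 263 without RA replicate 3. Amphioxus Wnt alone ran from 161 to 417, with 193 without Wnt replicate 1, 161 without Wnt replicate 2 and 199 without Wnt replicate 3. In the batch term model, calls ran from 4325 to 5593 for FGF, from 9612 to 13548 for Nodal, from 7110 to 11008 for RA and from 7556 to 11604 for Wnt.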

Other observations

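Among transcripts that changed at least 2-fold in all 4 zebrafish treatments, 335 rose and 88 fell, against 2.19 and 0.412 for independent lists. In mixed directions 66 moved, against 15.1. In amphioxus with the batch term, 112 gene models rose and 118 fell in all 4 treatments at the 0.05 level and 288 moved in mixed directions, against 12.7, 12.7 and 178 for independent lists. Independent lists are no chance level here, because treatments share controls, all 4 in zebrafish and Nodal, RA and Wnt in amphioxus. In the top 500, simulated unchanged groups had means of 16.5% and 13.0% called in 2 or more treatments. For independent lists these were 2.00% and 2.29%. Without the batch term and against all 6 controls, BL96810 rose by 1.07 ± 0.17 (log2, SE) with FGF, 2.67 ± 0.17 with Nodal, 2.28 ± 0.17 with RA and 1.31 ± 0.17 with Wnt. Its values with the batch term were 1.11, 2.63, 2.24 and 1.27. BL08150, at 3193 CPM over the 6 controls, fell to 2248 CPM with FGF, 1949 with Nodal, 2269 with RA and 1751 with Wnt, and its log2 fold changes with the batch term were -0.50, -0.72, -0.50 and -0.87.

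The test in this paragraph was chosen after its result was seen. Each amphioxus FGF library deviated from its group mean together with 1 of controls 4 to 6, FGF 1 with control 4, FGF 2 with control 5 and FGF 3 with control 6. The lowest of those correlations across gene models was 0.682 and the highest 0.700, whereas all others lay between -0.385 and -0.323. Deviations within a group sum to 0, so the negative values follow from the positive ones and are no separate support. A candidate explanation is a shared batch of embryos or day for each such couple, which the labels do not give. The number of FGF calls with blocks for these couples was 9916, against 5261 with the batch term alone.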
